A study of Homo sapiens with 4 samples.

How the data were processed

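The samples were 4 two-colour arrays of an Agilent whole human genome design, hybridised with RNA from HEC1B cells transfected with siADSL or control siRNA at 50 nM after seeding at 20% confluence, per the labels. For each array, 825 ng of each labelled cRNA were hybridised for 17 h at 65 °C, per the labels' protocols. The labels name 2 biological replicates, each measured on 2 arrays with the dyes swapped, and give no culture or passage. All 4 arrays lay on 1 slide and were scanned once, so slide and scan cannot differ between arrays.

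The scanner files hold spot intensity values from Agilent Feature Extraction 10.7.3.1, per the file headers and the submitters' processing notes. Mean signal and median local background per spot and dye are not normalized, per the file headers. The same files hold processed intensities that the software had background-subtracted, detrended and dye-normalized, and a log10 ratio of red over green, per the file headers. The authors' deposited value table holds log10 ratios. They equalled the scanner log10 ratio, turned to siADSL over control, for 100% of spots on every array within 0.0001, and the median of each column was 0. Array positions are those of the design build hg18, per the file headers.

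Each array held 43118 spots that were not controls, for 34127 probes. Median mean signals over these spots were 112 to 131 in Cy3 and 177 to 198 in Cy5, against median backgrounds of 31 to 35 and 41. No spot was saturated. Of the probes, 24827 were named through the unversioned RefSeq accession in a GRCh38.p14 table of genes. Another 1276 were named through a file name that is a current symbol and 500 through an older symbol. The remaining 7524 kept the name in the file.

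Analysis used R 4.3.3 with limma 3.58.1, statmod 1.5.0 and data.table (version 1.17.8), and figures used Python 3.11.15 with matplotlib 3.10.9 and pandas 2.3.3. Background was corrected with normexp (offset 50) on mean signal and median local background. Arrays were normalized by loess with control spots at weight 0. Spots marked by the software as outliers were left out, 0.979% to 1.25% per array, and spots of a probe were averaged. Spots marked for a non-uniform local background (0, 1, 7 and 19 per array) were left out before the normexp fit. This order was chosen after seeing the data, because 5 spots with background above 200 (up to 93062 in Cy3) distorted the fit of 1 array. They lay in rows 7 to 10 and columns 10 to 11 of the array with siADSL in Cy5 of replicate 2. The fit on all spots is an alternative below.

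A probe was kept when at least a share of 0.5 of its spots was well above background on all 4 arrays in the siADSL channel or on all 4 in the control channel. This left 20235 probes and 16125 genes, 13145 of them with a gene symbol. A gene took its probe with the highest mean intensity. Named genes whose other measured probes had the opposite sign included KLRF1, CCNB1, POLR1A and BCL2L11. Ratios were turned to siADSL over control, the 2 arrays of a replicate were averaged, and the 2 replicate means were tested against 0 with lmFit and eBayes (1 residual degree of freedom, prior degrees of freedom 1.86) and Benjamini-Hochberg adjustment at 0.05. The offset shrinks ratios of dim probes. Of the called genes, 80 were well above background on no array of one condition and have only a bound.

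Turned log ratios correlated across genes at r = 0.976 and 0.979 between arrays of the same dye orientation and different replicates. Between arrays of opposite orientation the mean r was 0.8434 within a replicate and 0.8430 between replicates. Genes are not independent replicates. The median SD between replicate means was 0.0160. The p-values therefore measure the spread between these samples, which may be technical.

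The 30 gene lists, the tests, the rule for named genes and most alternatives were fixed before the data were examined. Lists were tested with camera (preset correlation 0.01, at least 5 measured members) against all other genes. The same test with an estimated correlation, fry, and 10000 random lists matched on intensity (within 100 ranks) were set beside it. Named genes were ADSL, ASS1 and the measured KLRC genes, the 12 called genes with the largest change in each direction among those with a symbol and the same sign on 4 arrays, and in each list the 4 called members with the largest change, or 2 measured members where none was called. XIST and Y-linked genes were left out. This named 136 genes, of which the report prints a part.

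Alternatives were Agilent's processed signals, no background correction, median centring, Aquantile scaling, no filter, a filter on both channels, the mean of probes, eBayes with trend and robust variances, the 4 arrays with a dye term, each dye orientation alone, the authors' value table, and leaving out each replicate. Added after seeing the data were normexp on all spots, normexp on all spots but those of background above 200, a replicate block without a dye term, 4 arrays without dye term or block, 3 arrays without the one with the background artefact, and treat at 1.5-fold.

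The scripts were tested on simulated data for the comparison of siADSL with control, with 16125 genes, the measured dye effects and the fitted spread. Changed were 200 genes drawn at random and the members of a list, which were shifted lower by 0.25. Changes of 0.25 on the log2 scale were called in 74.6% of 67 genes, of 0.5 in 89.6% of 67 and of 1 in 97.0% of 66. Unchanged genes made up 7.25% of the calls. The list shifted lower by 0.25 in the simulation was called, and 0 other lists were. Simulated genes varied independently, with a smaller added spread between genes than the measured SD of 0.344. Far fewer genes were changed than the 79.1% called in the data. The simulation therefore does not give the rate of false list calls here.

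Sequence words of 7 bases in the 60-base probes were tested for a shift of the log2 ratio after regression on base composition and intensity, for words in at least 20 probes. Families of related genes were chosen after seeing the data.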

Results

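Gene expression was compared between HEC1B cells, a human endometrial adenocarcinoma line, given an siRNA against ADSL and HEC1B cells given a non-targeting control siRNA. ADSL encodes adenylosuccinate lyase, an enzyme of purine synthesis that releases fumarate. Both RNAs were hybridised together on each of 4 two-colour arrays. The arrays form 2 biological replicates of 2 arrays each, and the dyes were swapped within each replicate. Values are log2 ratios of siADSL over control, so a positive value means a higher level after siADSL. A value after ± is the SD over the 2 replicate means (n = 2). Each replicate mean averages both dye orientations, so this SD leaves out the difference between them, which can be much larger. Probes well above local background made up 58.7% to 63.2% of all probes in the siADSL channel and 60.2% to 61.3% in the control channel. After filtering, 16125 genes were measured. The number of arrays limits the precision of every value.

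The first question was whether the siRNA lowered its target. ADSL had the lowest log2 ratio of all measured genes, -3.50 ± 0.044 (SD, n = 2), an 11.3-fold lower level (limma adjusted p = 0.000421). The ratio lay between -3.61 and -3.44 on the 4 arrays. The only ADSL probe is placed by the array design on chromosome 22, from 39085216 to 39086370 of build hg18, a span longer than the 60 bases of the probe. The genotype field of the labels names ASS1 knockout and ASS1 wild-type cells, while the sample titles, source names and treatment text name siADSL and control siRNA. ASS1, the urea cycle enzyme argininosuccinate synthase, was higher with siADSL at 1.17 ± 0.087 (SD, n = 2; adjusted p = 0.000646). Its brightest probe lies on chromosome 9, from 132366422 to 132366481 of hg18, and a second ASS1 probe gave 0.89. The direction of all values below rests on the titles, and the low ADSL ratio runs the same way.

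The series title links ADSL to KLRC3, a gene of the killer cell lectin-like receptor family. KLRC3 and its neighbour KLRC4 were both lower with siADSL. KLRC3 was well above background on all 4 arrays in control cells and on 0 of 4 in siADSL cells, so only a bound can be given. Its bound from the means was 1.48-fold lower (fitted log2 ratio -0.62 ± 0.19, SD, n = 2, limma adjusted p = 0.00807). Replicate 2 alone had a smaller change, with a log2 ratio of -0.49. KLRC4 showed the same detection pattern, and its bound was 1.84-fold lower (fitted log2 ratio -0.90 ± 0.10, SD, n = 2, limma adjusted p = 0.00117). Its replicate 2 was at -0.83, again a smaller change than the bound. These bounds are estimates without a sampling error, not limits that each replicate meets. They set the control mean against the higher of the probe's own siADSL signal and the lowest signal among probes well above background. Signals were taken per channel after loess and Aquantile scaling. The KLRC3 probe spans 10459625 to 10460556 and the KLRC4 probe 10451507 to 10451566 on chromosome 12 (hg18). Neither KLRC1 probe was well above background on all 4 arrays of either condition. KLRC genes share long stretches of sequence, so cross-hybridisation between them was not excluded. Among the 7 measured genes of the receptor list, 2 rose, 3 fell and 2 were not called. KLRG1 was lower at -0.24 but was not called with siADSL in Cy5 alone (-0.09, adjusted p = 0.0688). KLRF1 was higher at 0.18, but 1 of its 4 arrays was below 0 and a second KLRF1 probe gave -0.03. Its call was lost with the mean of probes (adjusted p = 0.166), with siADSL in Cy3 alone (adjusted p = 0.254) and with 3 arrays (adjusted p = 0.0980). The list as a whole was not called (mean -0.20, median -0.01; camera adjusted p = 0.927). Ligands of natural killer cell receptors went both ways, with 4 higher and 4 lower of 9 (adjusted p = 0.933). NECTIN2 was higher at 0.45, and NCR3LG1, the ligand of NKp30, was lower at -0.54.

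Among called genes with a symbol and the same sign on all 4 arrays, the largest increase was in ADGRG1, an adhesion receptor, which rose 10.6-fold (log2 ratio 3.40 ± 0.026, SD, n = 2). PDZK1, a scaffold protein of membrane transporters, reached 3.01 ± 0.025, and LGALS2, a galectin, 2.97 ± 0.0010. SMIM24 rose to 2.86, CDH16, a cadherin, to 2.67 and CDKN1C, the cyclin-dependent kinase inhibitor p57, to 2.67. The other 6 of the 12 largest increases were FBXO2, MT1F, DPP4, HS6ST1, SPNS2 and YBX2, between 2.00 and 2.16. After ADSL, the largest decrease was in BIRC3, an inhibitor of apoptosis, at -2.56 ± 0.055 (5.90-fold). F2RL2, a thrombin receptor, was lower at -2.48 ± 0.072. The epidermal growth factor receptor ligands AREG and EREG were lower at -2.19 and -1.89, and a second AREG probe gave -1.49. SLC7A11, the cystine importer, fell by 1.83, the AP-1 subunit FOSL1 by 1.66 and ANKRD1 by 1.71. TM4SF19, PUDP, CREB5 and the small Cajal body RNA SCARNA9 lay between -1.91 and -1.80. Adjusted p values of these 24 genes lay between 0.000421 and 0.000445.

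**Figure D1:**
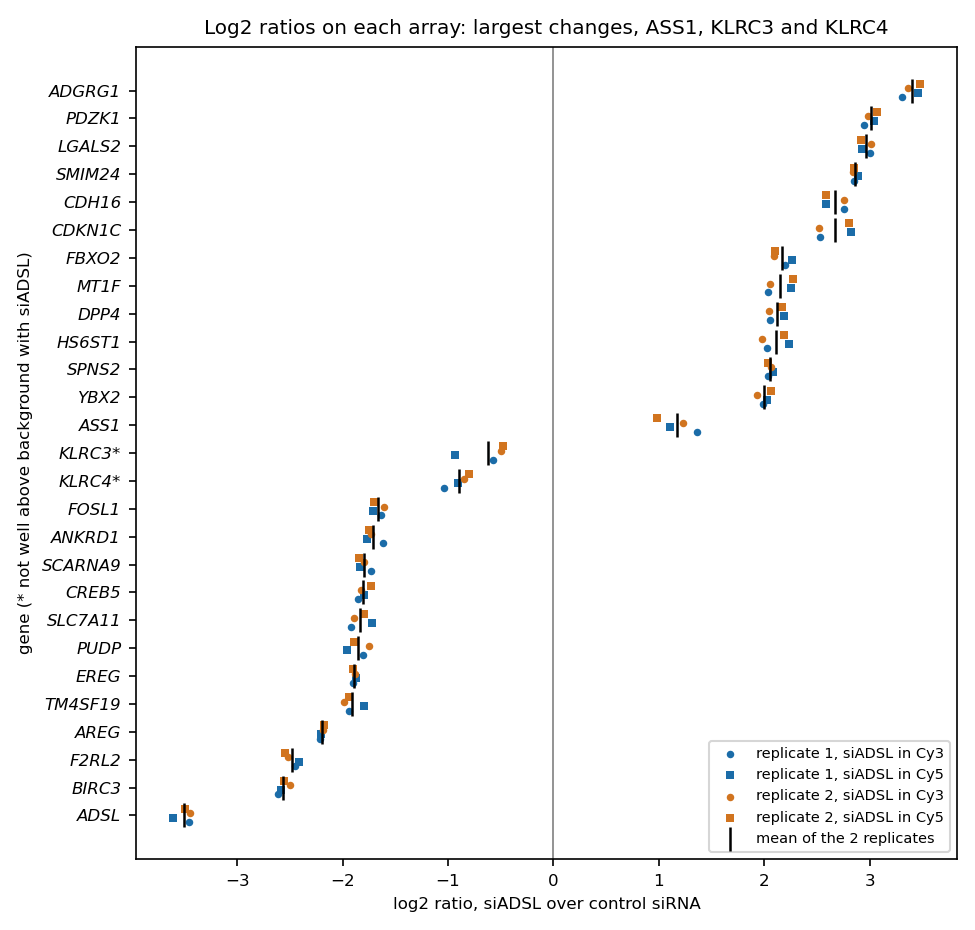
Log2 ratio of siADSL over control siRNA (x axis) for the 12 largest increases, the 12 largest decreases, ASS1, KLRC3 and KLRC4 (y axis), with circles and squares for the 2 dye orientations, a colour per biological replicate and a black bar at the mean of the 2 replicates. Means run from -3.50 for ADSL to 3.40 for ADGRG1, and the same sign on the 4 arrays was a condition for choosing the 24 genes.

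In all, 12761 genes were called (limma, adjusted p under 0.05), 79.1% of those measured, with 6782 higher and 5979 lower. Most changes were small: the median absolute log2 ratio was 0.17, and 1968 called genes lay within 0.1 of 0. A change of at least 2-fold was called for 283 genes, 189 higher and 94 lower. With Agilent's processed signals or the authors' value table it was called for 762 genes, and with normexp on all spots for 168 of 8102 called genes. Against a 1.5-fold threshold (limma treat, chosen after seeing the data), 796 genes were called, 542 higher and 254 lower. The 2 replicates differed by no more than repeated hybridisations did, so the p-values measure a spread close to technical. Higher genes made up 53.1% of calls with loess and 43.1% with median centring.

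Of 30 gene lists fixed before the data were examined, 5 were called by camera with a preset correlation, and all 5 were lower with siADSL. With an estimated correlation, which rests here on 1 residual degree of freedom, each had an adjusted p = 0.962.

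Genes of the NF-kB pathway and inflammation fell together. All 12 measured members were lower, and 7 fell by at least 1.5-fold (list mean -0.83, median -0.60, camera adjusted p = 0.000233, adjusted p = 0.962 with an estimated correlation). The size of the list mean depended on the processing, from -1.45 to -0.52 over 16 alternatives. Besides BIRC3 they included the NF-kB subunits RELB (-1.43 ± 0.024) and NFKB2 (-0.76 ± 0.0085) and the adhesion molecule ICAM1 (-1.16 ± 0.0091).

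Targets of NRF2, the regulator of antioxidant genes, were lower for 16 of 20 members, with 1 higher and 3 not called (mean -0.52, median -0.34; camera adjusted p = 0.000316; adjusted p = 0.962 with an estimated correlation). Next to SLC7A11, the largest decreases were in AKR1B10, an aldo-keto reductase (-1.44 ± 0.049), TXNRD1, thioredoxin reductase (-1.07 ± 0.021), and HMOX1, heme oxygenase (-1.07 ± 0.0077). The exception was NQO1, also a classical NRF2 target, which was higher at 0.27.

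Genes of the integrated stress response, targets of ATF4, were lower for 15 of 22 members and higher for 6 (mean -0.32, median -0.30; camera adjusted p = 0.0329; adjusted p = 0.962 with an estimated correlation). PSAT1, an enzyme of serine synthesis, fell by 1.16 and the glycyl-tRNA synthetase GARS1 by 0.70. ATF3 was lower at -0.80 on its brightest probe, while its 3 other measured probes lay between -0.11 and -0.0014. SLC7A11 belongs to this list and to the NRF2 list. This call was lost with Agilent's processed signals and the authors' value table (mean -0.38, adjusted p = 0.0622 with each) and with siADSL in Cy3 alone (mean -0.32, adjusted p = 0.0832), with a mean about as large or larger.

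Immediate early genes, which respond to growth factors, were lower for 12 of 16 and higher for 2 (mean -0.31, median -0.21, camera adjusted p = 0.0131, adjusted p = 0.962 with an estimated correlation). FOSL1 fell most (-1.66) and was the only member lower by at least 1.5-fold. It was followed by EGR1 (-0.55 ± 0.040), KLF4 (-0.52 ± 0.010) and the phosphatase gene DUSP1 (-0.50 ± 0.0019). On single arrays DUSP1 was at -0.67 with siADSL in Cy3 and between -0.34 and -0.33 with siADSL in Cy5. With siADSL in Cy3 alone the list was not called (adjusted p = 0.0832), although its mean was -0.30.

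Genes of the G2 phase and mitosis were lower for 19 of 26 and higher for 7 (mean -0.12, median -0.16; camera adjusted p = 0.0380; adjusted p = 0.962 with an estimated correlation). CCNB1, cyclin B1, was lower at -0.57 on its brightest probe, but another CCNB1 probe had the opposite sign. BUB1 fell by 0.46 and CDC20 by 0.38, while the motor protein gene KIF11 rose by 0.59. The call was lost with Agilent's processed signals and the authors' value table (mean -0.13, camera adjusted p = 0.0756 with each). It was also lost with siADSL in Cy3 alone (mean -0.11, camera adjusted p = 0.0841). Over 16 alternatives the list mean lay between -0.26 and -0.10.

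**Figure D2:**
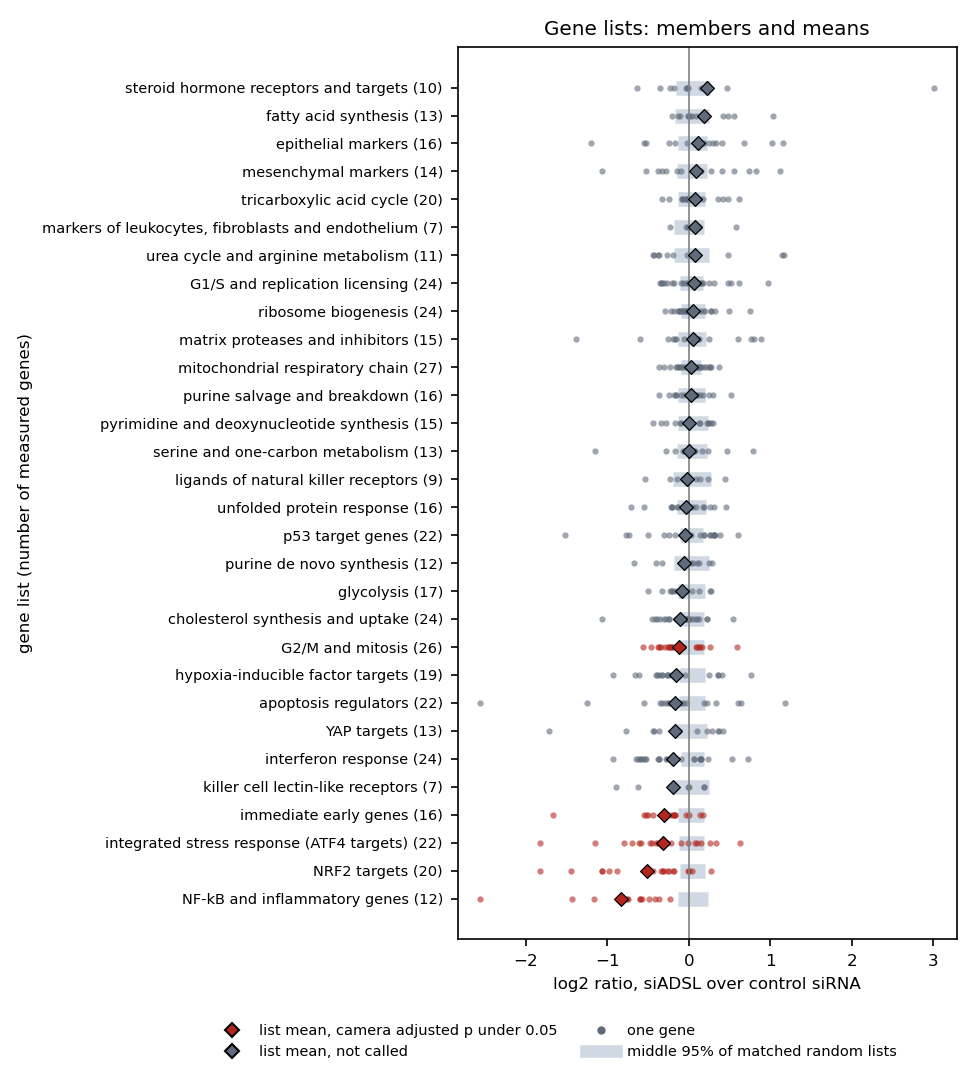
Log2 ratio of siADSL over control siRNA (x axis) of the measured members (dots) and the mean (diamonds) of each of the 30 gene lists (y axis, number of members in parentheses), with the middle 95% of 10000 random lists matched on intensity as bars. The 5 called lists, in red, have means from -0.83 to -0.12, left of their bars, as do 6 lists that were not called (interferon response, apoptosis regulators, hypoxia-inducible factor, YAP, cholesterol and killer cell lectin-like receptors).

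The pathway of the silenced enzyme did not move as a block. In purine de novo synthesis, 5 of 12 genes rose and 3 fell (mean -0.06, median 0.01; camera adjusted p = 0.933). PRPS1, which makes the ribose donor of purine synthesis, was lower at -0.68 ± 0.0030, IMPDH2 at -0.41 and ADSS2, the enzyme before ADSL in AMP synthesis, at -0.33, while PPAT, the committed step, was higher at 0.28. In purine salvage and breakdown 8 of 16 rose and 6 fell, with AMPD2 higher at 0.52 and NT5E lower at -0.36 (adjusted p = 0.939). Pyrimidine and deoxynucleotide genes were 7 higher and 6 lower of 15 (adjusted p = 0.939), among them UCK2 at -0.44. In the tricarboxylic acid cycle, where fumarate is an intermediate, 9 of 20 rose and 5 fell, with SUCLG1 at 0.62 and IDH3A at 0.49 (adjusted p = 0.933). In the urea cycle, 4 of 11 rose and 6 fell (mean 0.07, median -0.19; adjusted p = 0.766). Besides ASS1, CPS1, the carbamoyl phosphate synthetase that starts the cycle, was higher at 1.14 ± 0.017, and GOT2 was lower at -0.44. Serine and one-carbon genes split 6 to 7 of 13, with PHGDH higher at 0.78 and PSAT1 lower (adjusted p = 0.933).

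Other metabolic lists were not called. Glycolysis had 12 of 17 genes lower and 3 higher (adjusted p = 0.104), with ENO2 at -0.50. Targets of hypoxia-inducible factor had 14 of 19 lower and 5 higher (mean -0.16; adjusted p = 0.0862), led by ADM at -0.93, with the carbonic anhydrase CA12 higher at 0.76. Of the 27 respiratory chain genes in the list, 15 were higher and 10 lower, all within 0.37 of 0 (adjusted p = 0.927). NDUFA5, a respiratory chain gene outside this list, was higher at 1.30. For cholesterol synthesis and uptake, 11 of 24 were lower and 5 higher (adjusted p = 0.217), with INSIG1 at -1.07. Fatty acid synthesis had 6 of 13 higher and 3 lower (adjusted p = 0.766), with FADS2 at 1.03 and FASN at 0.55. Genes of the unfolded protein response were 7 higher and 7 lower of 16 (adjusted p = 0.933), with HSPA5 at 0.46 and EDEM1 at -0.71. Ribosome biogenesis genes were 9 higher and 11 lower of 24 (adjusted p = 0.933), MYC being higher at 0.49.

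Among cell state lists, G1/S and licensing genes were 11 higher and 9 lower of 24 (adjusted p = 0.933), and E2F2 (0.97 ± 0.012) and the cyclin E gene CCNE1 (0.62 ± 0.0091) were higher. Targets of p53 were 11 higher and 7 lower of 22 (adjusted p = 0.933), with GDF15 at -1.52 and BBC3 at 0.61. Apoptosis regulators had 14 of 22 lower and 6 higher (adjusted p = 0.104). BIK was lower at -1.25 and BCL2L11, which encodes BIM, higher at 1.18, with other BCL2L11 probes at 0.62 and -0.02. Interferon response genes had 15 of 24 lower and 6 higher (mean -0.20; adjusted p = 0.141), IRF7 at -0.93 and IFITM1 at 0.72. YAP targets were 6 higher and 7 lower of 13 (mean -0.18, median -0.13, adjusted p = 0.927), with ANKRD1 at -1.71 and CCN2 at -0.77. Epithelial markers were 10 higher and 5 lower of 16 (adjusted p = 0.766), JUP at 1.15 and KRT18 at -1.20 ± 0.0095. Mesenchymal markers were 7 higher and 6 lower of 14 (adjusted p = 0.939), TGFB1 being higher at 1.12. Matrix proteases and inhibitors were 7 higher and 6 lower of 15 (adjusted p = 0.956), PLAT at -1.39 and TIMP2 at 0.88. Steroid hormone genes were 3 higher and 4 lower of 10 (mean 0.22, median -0.03; adjusted p = 0.927), PDZK1 being the highest. Markers of leukocytes, fibroblasts and endothelium had 7 of 23 genes measured, 3 higher and 1 lower (adjusted p = 0.933), with COL1A1 at 0.58.

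For 27 of the 30 lists the counts of members called were the same adjusted over the list alone. The exceptions, adjusted over the list alone, were purine salvage with 9 higher and 7 lower, glycolysis with 4 higher and 12 lower, and interferon response with 7 higher and 15 lower. Mean, median and camera direction did not all share a sign for 6 lists: purine de novo synthesis, the urea cycle, p53 targets, the unfolded protein response, ribosome biogenesis and steroid hormone genes.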

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

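The test of the genotype field was chosen after the ADSL value was seen. The tests of dye bias and of replicate structure were chosen before the data were examined, and those of the lists after the list calls and before their own outcome.

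Of 173 values compared over the 4 arrays, 4 had 1 array far from the other 3, measured as its gap to the nearest array over the whole range. Chance alone gives about 1 in 20 where the 4 values differ only at random. Dye effects pair the arrays by orientation, so this rate need not hold here. NCR3LG1 was at -0.42 with siADSL in Cy5 of replicate 1 and between -0.58 and -0.57 on the others (gap 0.923 of the range). IRF7 was at -0.89 with siADSL in Cy3 of replicate 1 and at -0.95 on the others (0.967). BMF was at 0.52 with siADSL in Cy5 of replicate 2 and between 0.67 and 0.70 on the others (0.8292). Its bound from the means was 1.56-fold higher with siADSL, equal to its fitted fold change. The highest local Cy3 background was 93062 on the array with siADSL in Cy5 of replicate 2, against 45 to 110 on the others (0.999).

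Ratios correlated across genes between the 4 arrays, and 68.5% of genes had the same sign on all 4. Dye bias would turn the sign with the dye, and the lowest correlation across genes between arrays of opposite dye and different replicates was 0.842, which argues against it as the main source. A dye effect was still called for 8360 genes, with an SD over genes of 0.0973 against 0.344 for the siADSL effect. The mean correlation within a replicate exceeded that between replicates by 0.000394, which is what 1 pair of extracts hybridised 4 times would give, although 2 very similar cultures could give it too, and the small p-values in the report are then mainly technical. Matches of the siADSL seed to other transcripts stay open: among 7-base words, the lowest adjusted p on the lower side was 0.120, but only 60 bases per transcript were searched, and a shift of -0.2 would have passed for 53.2% of the 12034 words.

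The 5 called lists (NF-kB, NRF2, immediate early, ATF4, mitosis) were lower on every array, the highest of the 20 list means on single arrays being -0.10, so a dye effect does not account for their direction. Intensity of the members does not either, since the list means lay at or below percentile 1.19 of random lists matched on intensity. Of the lists not called, interferon, apoptosis and hypoxia lay at percentiles 0.08, 0.49 and 0.84. A hypothesis for the lower lists is a response to the loss of ADSL, but 1 siRNA treatment against 1 control siRNA cannot separate this from off-target effects of either siRNA.

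The genotype field names ASS1 knockout cells where the titles name siADSL. ADSL had rank 1 from the lowest ratio of all genes and ASS1 was higher, which argues against a comparison of ASS1-knockout with wild-type cells in place of the titled one. The test does not cover cells that differed in ASS1 genotype as well as in siRNA. The higher ASS1 ratio therefore cannot be assigned to siADSL alone. Whether the field was copied from another record was not tested.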

How the results depend on the processing

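The comparisons with normexp on all spots or without 5 spots, the replicate block, 4 arrays without dye term, 3 arrays and treat were chosen after seeing the data. ADSL lay between -4.02 and -3.00 under 19 alternatives and was called in each that has a test. It lay between -3.53 and -3.47 without one replicate, where no test is possible. Aquantile scaling leaves ratios as they are and tests nothing, and a value without one replicate always lies within 1 SD of the mean. The planned fit with both a dye term and the replicate as a block was not made, because limma gave no estimate of the correlation for 4 arrays and 2 coefficients. The arrays do hold a replicate contrast and its interaction with dye, and the ratio of their median squares was 0.993. The replicate block without a dye term (correlation -0.89) gave 13609 calls. Apart from the settings named next, counts of called genes lay between 9594 and 13609.

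Normexp on all spots gave 8102 calls, 3486 of them lower, and 168 of at least 2-fold. With only the 5 spots of background above 200 left out first, 12761 genes were called, all shared with the reported calls, so the difference comes from these 5 spots. Treat at 1.5-fold gave 796 calls, 542 higher and 254 lower. Agilent's processed signals and the authors' value table each gave 762 genes of at least 2-fold and 3 gene lists. These values differ from the chosen ones in several steps at once, and the cause was not tested. Gene lists called were 2 with siADSL in Cy3 alone, 0 with an estimated correlation (0 at an unadjusted p under 0.05) and 24 by fry, which does not compare a list with other genes. The NF-kB and NRF2 lists were called under all 16 other values or fits (camera adjusted p up to 0.000862 and 0.00398). Immediate early genes were called under 15, ATF4 targets and mitosis under 13. These settings are not independent checks. Aquantile scaling and eBayes with trend and robust variances do not alter the list test. The value table repeats the processed signals, and leaving out the 5 spots nearly repeats the reported values.

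Cholesterol genes were called with median centring (adjusted p = 0.0464) and interferon genes on 4 arrays without dye term or block (adjusted p = 0.0335). No list whose mean changed sign was called. With Agilent's processed signals, natural killer ligands moved to 0.023 and matrix proteases to -0.027, as with the value table. With median centring, means were -0.081 for purine salvage, -0.12 for pyrimidine synthesis, -0.046 for the tricarboxylic acid cycle, -0.035 for the urea cycle, -0.061 for G1/S, -0.099 for the respiratory chain, -0.0048 for matrix proteases and -0.080 for ribosome biogenesis. Serine and one-carbon genes were at 0.0037 without a filter and 0.016 with siADSL in Cy5 alone. Receptor genes were at 0.025 with the strict filter, which leaves out KLRC3 and KLRC4. Pyrimidine genes were at -0.012 with the mean of probes and -0.020 with siADSL in Cy3 alone, where natural killer ligands were at 0.0052. Apart from the receptor genes, the cause was not tested. Of single named genes, over the settings that have a test and without Aquantile scaling, 2136 values kept their sign and their side of the threshold. Another 20 lost the call, and 0 called ones changed sign. Most named genes were chosen for being called on these same arrays, so these counts are little evidence of stability. Dim probes such as those of KLRC3 and KLRC4 are limited by signal over background.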

Other observations

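The gene families and words here, and the tests on them, were chosen after the main results were seen. Families were tested with camera over 7 groups.

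Genes of cytosolic ribosomal proteins were higher with siADSL: 73 of 77 were called higher and 1 lower, where 79.1% of all genes were called. Their mean was 0.28 (camera adjusted p = 3.67e-11, adjusted p = 0.327 with an estimated correlation). The middle 95% of random lists matched on intensity ran from 0.020 to 0.149, so equally bright genes also tended above 0, though less. The mean was 0.17 on both arrays with siADSL in Cy3 and 0.39 to 0.40 with siADSL in Cy5, and stayed above 0 with Agilent's processed signals (0.193) and median centring (0.195). All 5 measured UDP-glucuronosyltransferase genes, which encode conjugating enzymes, were higher (mean 1.23; adjusted p = 0.00675; adjusted p = 0.327 with an estimated correlation), UGT2B7 most, at 1.46. UGT genes share sequence, so their probes are not independent. Of 20 collagen genes, 14 were higher and 5 lower (mean 0.35; adjusted p = 0.0478; adjusted p = 0.327 with an estimated correlation), with COL6A1 at 1.61. Metallothioneins split: MT1F was higher at 2.15, while the other 7 measured were called lower, from -0.64 for MT2A to -0.32 for MT1A. The family mean was -0.16, inside the middle 95% of matched random lists (percentile 6.26), and the median -0.46 (adjusted p = 0.0105; adjusted p = 0.327 with an estimated correlation), and these genes share sequence too. The sign of each family mean in this paragraph was the same with Agilent's processed signals, no background correction, median centring and normexp on all spots.

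Of 8 ERBB receptor ligands, 5 were lower and 1 higher (mean -0.66, median -0.19; adjusted p = 0.0478; adjusted p = 0.327 with an estimated correlation), but AREG and EREG prompted the choice of this family. Without them the mean of the other 6 was -0.20 (camera unadjusted p = 0.284), inside the middle 95% of matched random lists (percentile 3.49), with 3 lower, NRG4 most (-0.93), and 1 higher. A hypothesis was that lower ERK output goes with lower AREG and EREG and with the immediate early genes. The 9 measured of 10 ERK output genes named before their values were seen had a mean of -0.165, at percentile 5.07 of matched random lists. EPHA2 was at -0.58 and PHLDA1 at -0.46, but CCND1 and SPRY2 were higher, at 0.18 and 0.17. The mean may point to lower ERK output but did not leave the middle 95% of random lists, so the hypothesis stays open.

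The lower NRF2 list might come from genes that ATF4 also controls. Only SLC7A11 was in both lists, and without it the mean of the other 19 was -0.45, at percentile 0 of 10000 matched random lists. The low mean thus did not rest on SLC7A11 alone. With so little overlap, leaving out the shared gene could hardly have removed the shift, so this does not decide whether ATF4 contributed. Regulation by ATF4 of genes outside the ATF4 list was not tested.

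Probes with the word GCAGTAC had higher ratios with siADSL. It had the lowest adjusted p of 12034 words of 7 bases, with a shift of 0.39 over 35 probes (adjusted p = 3.10e-07), and 29 of the 35 were above 0. Only 2 other words passed, both on the higher side. The highest were EMP2 (1.69), FOXO3 (1.37), NDUFA5 (1.30) and YWHAH (1.16), chosen after their values were seen. The shift was 0.315 or more on each of the 4 arrays, which argues against dye-dependent hybridisation. A candidate explanation is a seed match of the control siRNA, which would lower these transcripts in control cells. Neither of its predictions was met: the 12 probes with a following A had a mean of 0.41 against 0.43 for the other 23, and the reverse complement GTACTGC had a shift of 0.154 (adjusted p = 0.678), above the limit set for this explanation. It was below the limit set against it. The siRNA sequences were not used here, so the source of the shift stays open.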
